A study of Rattus norvegicus with 6 samples.

How the data were processed

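Kidney RNA of male rats was sequenced in 6 libraries, 3 from Dahl salt-sensitive (Dahl SS) controls and 3 from Resp18 mutants. Per the labels' protocols, the diet was changed to one with 2% salt at 6 weeks of age, kidneys were taken after 1 week at 7 weeks of age, and libraries were made with a NEBNext Ultra kit from 3 ug of total RNA. Poly(A) selection, strand marking and the handling of reads that map to several places are not given in the sources used here. Whether the counts keep apart reads of overlapping or antisense models, and of near-identical gene copies, is therefore not known. The labels do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries.

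The authors deposited a table of whole-number read counts per gene model and a table of FPKM values for the same models. The submitters' processing notes name CASAVA 1.8, HISAT2 2.1.0 and HTSeq 0.6.1 and the rat build Rnor 5.0, without saying what each was used for. The tables hold 28787 gene models, of which 26689 carry an Ensembl rat identifier and 2098 carry a number in its place, as Novel00526 does. How these numbered models were made is not given in the sources used here. No row named anything other than a gene model. For each of the 117134 nonzero values, the deposited FPKM equalled the count scaled by the library's total count and by a whole-number length, with the implied lengths whole to within 1e-04 bases. The FPKM table therefore adds a length for each detected model, and no separate measurement of abundance. The median length over tested models was 2008 bases. A summary of models per FPKM interval was not used.

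The count and FPKM tables give identifiers and no gene names, and the reference table of rat genes supplied for names matched 0 of the 26689 Ensembl identifiers. Names were therefore not assigned, and models are given by the identifiers in the tables. The planned reading of Resp18 itself, of the renin-angiotensin members, of 22 pathway lists and 17 cell type marker lists, and of clustering along chromosomes was not analysed here for this reason. No genome position is given for any model.

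Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Models were kept with filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 16324 models, 14622 with an Ensembl identifier and 1702 without, holding 99.9% of all counts. Libraries were scaled with TMM factors, and mutants were compared with controls by the quasi-likelihood F test on group alone, with Benjamini-Hochberg adjustment (FDR) over all tested models and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of F, and 95% intervals used the test's degrees of freedom (median 8.95). CPM values were computed on the TMM-scaled library size. Single values per library were compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow. The rule fixed before the data were examined named genes by symbol and so named none. The 2 models past the threshold, and 1 further higher and 1 further lower model, were chosen after their values were seen. The further pair had the largest positive and negative DESeq2 fold change among models that DESeq2 called and edgeR did not, with a mean of at least 1 CPM and no overlap between the groups.

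Total counts ranged from 13427302 to 22854561 per library, and the biological coefficient of variation was 14.4%. The test was tried on simulated data drawn from the means, library sizes and dispersions of the 16324 models in this comparison, in 5 simulations with 200 changed models each. In these, edgeR recovered 34.0% of the models changed 1.5-fold, 64.0% of those changed 2-fold, 92.0% of those changed 4-fold and 96.8% of those changed 8-fold. Of edgeR's simulated calls 7.84% were false, and of DESeq2's 15.3%. DESeq2 recovered 43.2%, 68.8%, 92.4% and 96.4% at the same folds. The models were drawn independently, without a length trend between libraries, and the 200 changed models eased the cutoff that the FDR adjustment sets. These shares may therefore not hold for the real comparison.

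Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), robust quasi-likelihood estimation, 3 other scalings, 2 other filters, the replicate number as a block, each library left out in turn, other thresholds, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no filter. Alternatives chosen after seeing the data were edgeR's newer dispersion estimate, removal of a length trend in each library, and leaving out both libraries at the ends of that trend. The trend was fitted by loess of each library's log2 CPM deviation (prior count 2) on log10 length and entered as offsets. On simulated counts with a slope of 0.3 per log10 length, the fitted slopes were within 0.0255 of the given ones.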

Results

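RNA was sequenced from kidneys of 7-week-old male rats after 1 week on a 2% salt diet. The controls were Dahl salt-sensitive (Dahl SS) rats, an inbred strain whose blood pressure rises with dietary salt. The other group carried a mutation in Resp18, which encodes regulated endocrine-specific protein 18, a protein of neuroendocrine cells. Each group had 3 libraries. The Dahl SS libraries held 22854561, 14497217 and 16251658 counted reads (replicates 1 to 3), and the mutant libraries held 21958869, 20834064 and 13427302. Between 19306 and 19853 gene models had at least 1 read in a library, and 21608 of 28787 had a read in any library.

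Rank correlations of log2 CPM over 16324 tested models were 0.985 to 0.991 for the 6 pairs of libraries within a group and 0.977 to 0.991 for the 9 pairs between groups. The chi-square of the counts per degree of freedom was 7.26 to 32.9 within groups and 6.92 to 92.2 between groups, so no pair was a repeat of one library. The 10 most abundant models took 9.60%, 13.2% and 11.5% of counts in the Dahl SS libraries and 15.8%, 12.8% and 11.8% in the mutant libraries (two-sided exact permutation p = 0.4). The most abundant single model took 2.92% ± 0.654 and 3.42% ± 1.01 (SD, n = 3, exact permutation p = 0.5). Models without an Ensembl identifier took 2.40% ± 0.138 in Dahl SS and 2.27% ± 0.0700 in mutant kidneys (SD, n = 3, exact permutation p = 0.2). The difference in the share of models without an Ensembl identifier, mutant minus Dahl SS, was -0.134 percentage points and -0.0547 without Dahl SS replicate 1. That of the 10 most abundant models was 2.02 percentage points, 0.861 without mutant replicate 1 and 1.10 without Dahl SS replicate 1. None of the differences over all libraries was larger than the spread between libraries by that test, which cannot give a p under 0.1 with 3 against 3. The first principal component of log2 CPM held 33.3% of the variance and ran from Dahl SS replicate 1 at -41.1 to mutant replicate 1 at 31.8. On it, Dahl SS replicate 2 at 4.87 lay among mutant replicates 2 and 3 at 3.79 and 9.01. The second component (21.2%) set it apart from them, with Dahl SS replicates 1 to 3 at 4.14, -33.4 and -7.46. Mutant replicates 1 to 3 lay at 0.890, 15.5 and 20.3 on the second component.

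The comparison of mutant with Dahl SS kidneys asks which kidney transcripts differ between these groups on the salt diet, and the series title names the renin-angiotensin system. All libraries share this diet, so no effect of salt can be read from them. The groups are separate rat lines, so a difference may come from other variation between the lines as well as from the Resp18 mutation. The tables identify models without gene names. The Resp18 transcript was planned as a check on the labels, though a mutation need not lower the transcript of its gene. For lack of names, neither it nor the renin-angiotensin genes could be picked out. Any of them with an identifier that passed the filter were tested without a name. Of 16324 models, 1 fell and 1 rose by edgeR's quasi-likelihood test at an FDR of 0.05. Whether either is Resp18 or a renin-angiotensin gene was not determined, since no names were assigned. The count of 2 became 13 without Dahl SS replicate 1, 1 without Dahl SS replicate 2 and 6 without mutant replicate 3. ENSRNOG00000019704, with a length of 719 bases, fell 19.9-fold in mutants (95% interval 14.4 to 27.6; log2 fold change -4.32 ± 0.21 SE, edgeR adjusted p = 0.000117). It stood at 11.3 ± 0.997 CPM in Dahl SS and 0.568 ± 0.0890 CPM in mutant kidneys (SD, n = 3), from 242, 177 and 181 reads in the controls and 12, 10 and 9 in the mutants. ENSRNOG00000047786, with a length of 1206 bases, rose 8.04-fold (95% interval 5.02 to 12.9; log2 fold change 3.01 ± 0.30 SE, edgeR adjusted p = 0.0297). It stood at 1.60 ± 0.311 CPM in Dahl SS and 12.7 ± 4.74 CPM in mutant kidneys (SD, n = 3), from 32, 28 and 24 reads against 191, 376 and 152. In each of the 2 models, every mutant library lay on the same side of every control library. The fall was past the threshold under all 23 alternatives run. The rise was lost with limma-voom (adjusted p = 0.2506), in 3 limma settings on log2 FPKM (adjusted p from 0.0707 to 0.2073), and without Dahl SS replicate 2 (edgeR adjusted p = 0.0577) or Dahl SS replicate 3 (edgeR adjusted p = 0.301), and its adjusted p ranged from 2.90e-19 to 0.301 over its 23 alternatives.

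**Figure D1:**
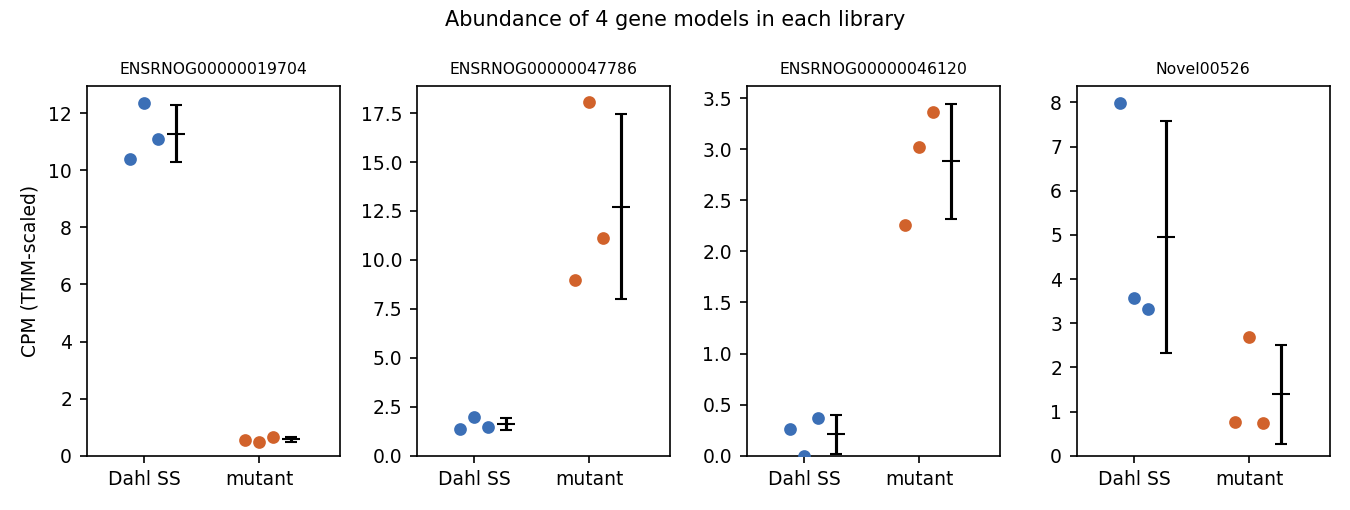
CPM (TMM-scaled, linear axis from 0, a separate scale per panel) of 4 gene models in each library of Dahl SS (blue) and Resp18 mutant (orange) kidneys, 1 point per library, with the mean and SD in black (n = 3). ENSRNOG00000019704 lies between 10.4 and 12.4 CPM in controls and between 0.480 and 0.658 CPM in mutants, and ENSRNOG00000047786 between 1.37 and 1.96 CPM in controls and between 8.99 and 18.0 CPM in mutants.

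A further model with a large difference was ENSRNOG00000046120, with a length of 835 bases, at 0.209 ± 0.189 CPM in Dahl SS and 2.88 ± 0.566 CPM in mutant kidneys (SD, n = 3). It had 6, 0 and 6 reads in the controls and 48, 63 and 46 in the mutants, and a log2 fold change of 3.66 ± 0.53 SE. It did not pass edgeR's quasi-likelihood test (adjusted p = 0.217) and passed DESeq2 (adjusted p = 2.81e-07), and its adjusted p ranged from 2.81e-07 to 0.8245 over 23 alternatives. Its log2 fold change ranged from 1.83, with limma on log2(FPKM + 1), to 4.16, with limma-voom. Novel00526, a model without an Ensembl identifier and with a length of 2126 bases, was at 4.95 ± 2.63 CPM in Dahl SS and 1.39 ± 1.12 CPM in mutant kidneys (SD, n = 3), with 186, 51 and 54 reads against 16, 56 and 10. Its log2 fold change was -1.81 ± 0.54 SE, with an adjusted p of 0.348 in edgeR and 0.0263 in DESeq2, and a range from 0.0102 to 0.8245 over 23 alternatives. The log2 fold change ranged from -2.74, without mutant replicate 2, to -0.93, without Dahl SS replicate 1 and mutant replicate 1. Both models were picked among those that DESeq2 called and edgeR did not, without overlap between the groups. Their selection fixed these outcomes, which are no support for a change.

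Across the remaining models, differences were mostly small. The central 95% of log2 fold changes lay between -0.55 and 0.69, and the median absolute value was 0.15 against a median standard error of 0.14. For 13679 models (83.8%) the 95% interval of the fold change lay inside a 2-fold change in either direction. This share depended on abundance: it was 7.98% of the 978 models at or under 0 log2 CPM, 54.4% of the 2895 models between 0 and 2, and 92.7% of the 4014 models between 2 and 4. It was 98.1% of 5158 models between 4 and 6, 98.9% of 2716 between 6 and 8, and 99.1% of 563 above 8. The median standard error was 0.46 at or under 0 log2 CPM and 0.09 above 8. At an unadjusted p under 0.05, edgeR gave 1767 models, 926 higher and 841 lower in mutants, where 816 are expected by chance. With 1 library left out this count ranged from 1078, without mutant replicate 1, to 2499, without Dahl SS replicate 2. Grouping Dahl SS replicates 1 and 3 with mutant replicate 2 gave 2048, so a count above 816 is not particular to the grouping by genotype. The 4 splits into 3 and 3 that kept Dahl SS replicate 1 with mutant replicate 1 gave 191 to 256. The groups did not overlap in 2800 models (17.2%), 1418 higher and 1382 lower, where chance gives 10% for 3 against 3. Another split of the same 6 libraries into 3 and 3 separated 2937 models, and the 4 splits that kept Dahl SS replicate 1 with mutant replicate 1 separated 773 to 940.

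The number of changed models depended on the tool. DESeq2 on the same counts called 105 models at an adjusted p under 0.05, 58 higher and 47 lower in mutants, including both edgeR calls, and gave no adjusted p for 963 models. With the length trend of each library removed, a setting chosen after seeing the data, DESeq2 called 279 models, 147 higher and 132 lower. With the same trend removed edgeR called 3. In the simulated data 15.3% of DESeq2's calls were false. Of the 105 models, 88 carry an Ensembl identifier and 17 do not. Their absolute log2 fold changes had a median of 0.68, and 17 changed at least 2-fold. Each of the 105 had an unadjusted edgeR p under 0.05, and 102 separated the groups without overlap. Their selection by DESeq2 on the same libraries favours both outcomes, so neither is independent support for the calls. The higher models called by DESeq2 had a median log2 fold change of 0.72 and the lower ones of -0.60.

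**Figure D2:**
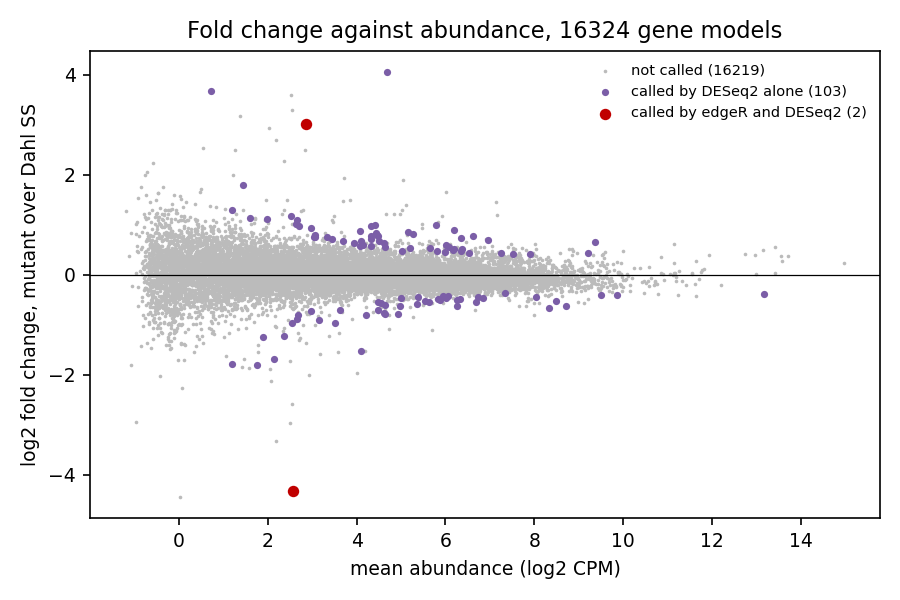
Log2 fold change of Resp18 mutant over Dahl SS kidneys (vertical axis) against mean abundance in log2 CPM (horizontal axis) for 16324 gene models, 1 point per model. Of the models called by DESeq2, 2 were also called by edgeR (red, log2 fold changes -4.32 and 3.01), and the rest (purple) lie mostly within 1 log2 unit of 0.

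Fold changes went with the length of the model. The median log2 fold change was 0.17 in the 628 models of up to 500 bases, 0.14 in the 1869 of 500 to 1000 bases, -0.06 in the 3132 of 3000 to 5000 bases and -0.11 in the 1240 over 5000 bases. Across models the Spearman correlation of fold change with length was -0.26, where models are not independent replicates. Libraries of the same group differed in this respect. The correlation of a library's deviation with length was 0.37 in Dahl SS replicate 1, -0.17 in replicate 2 and 0.04 in replicate 3, and -0.37, 0.04 and -0.01 in mutant replicates 1 to 3. These library values averaged 0.0794 ± 0.272 in Dahl SS and -0.115 ± 0.224 in mutants (SD, n = 3, exact permutation p = 0.4). Without Dahl SS replicate 1 and mutant replicate 1, the correlation of fold change with length across models was 0.07. In that setting edgeR called 22 models at an adjusted p under 0.05, 9 higher and 13 lower, which include the 2 calls over all libraries. These 2 libraries were picked after their values were seen and lie at the ends of the first principal component. Leaving them out can narrow the spread within groups, so the higher count is no support for more changed models.

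**Figure D3:**
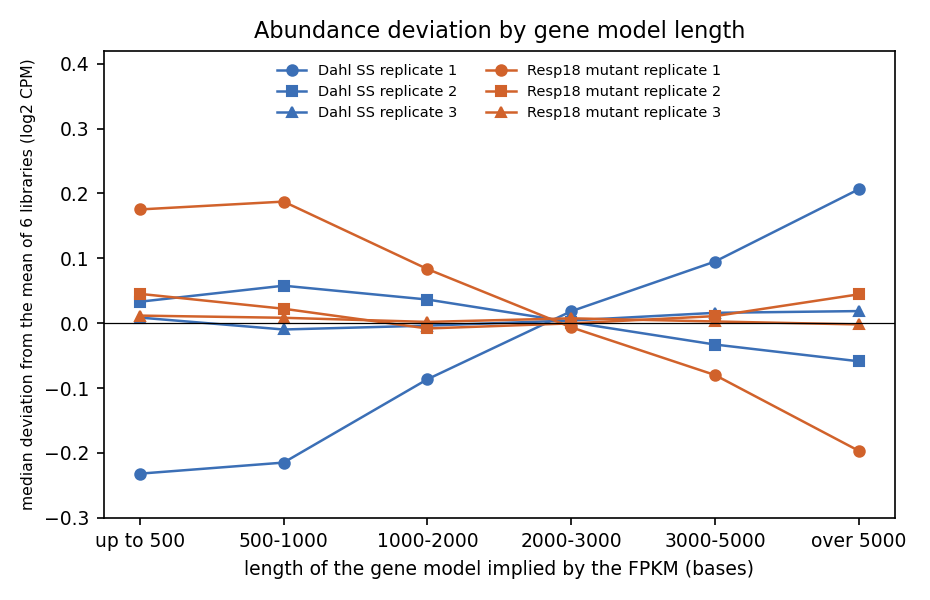
Median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) by class of gene model length in bases (horizontal axis), with 1 line per library, Dahl SS in blue and Resp18 mutant in orange. Dahl SS replicate 1 runs from -0.23 in the shortest class to 0.21 in the longest, and mutant replicate 1 from 0.18 to -0.20, while the other 4 libraries stay closer to 0.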

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

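Chosen after seeing the data were edgeR's newer dispersion estimate (2 models), the length corrections in edgeR (3) and DESeq2, the removal of both libraries at the ends of the length trend, and the alternatives for the shares of counts. The count of 2 changed models was within 1.5 times of itself under 14 of 24 alternatives. Among them were robust estimation, the other scalings and both other filters. The stricter fold threshold and an FDR of 0.10 also gave 2. The main fit fixed both outcomes, since both calls changed by more than that threshold and the third lowest FDR was 0.163. Without Dahl SS replicate 3 the count was also 2, both lower, but only 1 was shared with the main fit. The count was 105 with DESeq2 (58 higher, 47 lower), 1 with limma-voom, 1 with limma on log2(FPKM + 1), 1 on log2(FPKM + 0.1) and 1 on log2(FPKM + 1) with no filter. With 1 library left out it ranged from 1 to 13: 13 without Dahl SS replicate 1, 1 without Dahl SS replicate 2 and 6 without mutant replicate 3. DESeq2 with the length trend removed gave 279 models and edgeR without both libraries at the ends of that trend gave 22. The cause was not tested. The titles number both groups 1 to 3, and same-numbered libraries did not deviate together (correlations of deviations -0.274, -0.144 and -0.00176), so they are not taken as pairs. With the replicate block edgeR called the same 2 models, and its unadjusted count fell from 1767 to 885. The fold change of ENSRNOG00000019704 ranged from -4.47 to -3.23 (log2) and held its call in 23 of 23 alternatives. That of ENSRNOG00000047786 ranged from 2.26 to 3.22 and kept its direction in all 23, with the call lost in 6. The share of models with an interval inside 2-fold was 63.5% with no low-count filter. Alternatives for the gene lists, single named genes and chromosomes were not run, since identifiers were not paired with names. Intervals were widest in models under 2 log2 CPM, and no alternative varied the depth.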

Other observations

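The tests of the length trend over the other 4 libraries and of abundance, and the splits of the libraries for the main edgeR and the DESeq2 counts, were chosen after the results they measure were seen, as were the length correction and the removal of both end libraries as settings.

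Over all 6 libraries, fold changes of mutants over controls were higher in short gene models than in long ones, while the library correlations with length did not separate the groups (0.0794 ± 0.272 in Dahl SS and -0.115 ± 0.224 in mutants, SD, n = 3, exact permutation p = 0.4). Over the other 4 libraries, without Dahl SS replicate 1 and mutant replicate 1, the correlation of fold change with length was 0.067. Those 2 libraries were picked for their own length correlations, so this value does not decide whether they are the source. A genotype effect present in every mutant library also stays open: the correlation reached 0.136 among the 9 mutant against control pairs, which met the bound set beforehand, but the 2 pairs above 0.1 share Dahl SS replicate 2. Dahl SS replicate 3 with mutant replicates 2 and 3 gave -0.00659 and -0.0272, and the pairs at -0.1 or lower, from -0.226 to -0.398, all hold Dahl SS replicate 1 or mutant replicate 1. Abundance differences between short and long models leave the trend in place, since the median correlation within 5 equal groups of models by abundance was -0.225. This criterion replaced a stricter one after its result was seen: the first asked for -0.1 or lower in each of the 5 groups and was not met, at -0.07 in the least abundant group, while the others ran from -0.14 to -0.46. It was replaced because low counts are the noisiest (median standard error 0.457 at or under 0 log2 CPM), so the evidence against abundance does not cover the least abundant models. A difference in RNA integrity or library fragment size between single libraries is a candidate explanation that the tables used here do not test.

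The number of changed models was 2 by edgeR and 105 by DESeq2. Of the 10 splits of the 6 libraries into 3 and 3, 4 gave at least 2 edgeR calls with a highest other count of 2, and 1 gave at least 105 DESeq2 calls with a highest other count of 30; 10 splits are too few for a share under 0.05. Of the 105 DESeq2 calls, 100 stayed called with the fitted length trend removed, among 279 in all. The fit took 1 curve per library at every abundance. The correlation of fold change with length ran from -0.07 in the least abundant group of models to -0.46 in the most abundant. Part of the trend may therefore remain, and the count of 100 does not decide whether it is the source of these calls. With the trend removed edgeR called 3 models, a count that 1 of the 10 splits reached (highest other 2). What stays open is whether the excess of small p-values reflects genotype or the structure of the libraries: the 6 splits that part Dahl SS replicate 1 from mutant replicate 1 gave 469 to 2048 models (2048 for Dahl SS replicates 1 and 3 with mutant replicate 2) at an unadjusted edgeR p under 0.05, with 1767 for the real split, and the 4 splits that keep them together gave 191 to 256. With the length trend removed, the real split gave 2079 such models and the highest other split 1770.

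Among models called by DESeq2, those without an Ensembl identifier (numbered models) were mostly lower in mutants, 16 lower and 1 higher, against 31 lower and 57 higher among Ensembl models (two-sided Fisher exact p = 5.49e-06, where models are not independent). Over the other 4 libraries 9 of 12 calls on numbered models (75.0%, exact 95% interval 42.8 to 94.5) were lower, against 35 of 75 on Ensembl models (two-sided Fisher exact p = 0.118). With the length trend removed 24 of 32 (75.0%, interval 56.6 to 88.5) were lower, against 108 of 247 (two-sided Fisher exact p = 0.00113). These intervals and Fisher tests take models as independent and do not measure the spread between libraries. Both shares leave open how much of the pattern comes from the length trend or from those libraries. Over all tested models, the median log2 fold change of the 1702 numbered models was -0.07 against 0.01 for the Ensembl models, a gap of -0.0807 (camera p = 0.00828 with a preset correlation, p = 0.271 with an estimated correlation). With the length trend removed this gap was -0.069. The median lengths were 2161.5 bases in numbered and 1995 bases in Ensembl models, so removing a length trend could be expected to move the gap little. The gap of -0.069 therefore does not decide whether the length trend is the source. Over the other 4 libraries the gap was 0.012, as a gap that comes from the 2 libraries at the ends of the length trend would give. Those 2 libraries were picked after their values were seen. They also held the highest and lowest median deviation of numbered models, 0.111 in Dahl SS replicate 1 and -0.106 in mutant replicate 1. Leaving them out could shrink such a gap whatever its source, so the value of 0.012 does not decide whether they are the source. Whether numbered models hold transcripts that differ between the rat lines was not tested.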
